A study of Rattus norvegicus with 4 samples.

How the data were processed

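Long noncoding RNA (lncRNA) profiles were measured by RNA sequencing in astrocytes grown from the cerebral cortex of newborn Wistar rats. The astrocytes sat on coverslips above neurons and were kept apart from them, per the labels' protocols. The 4 libraries form 2 groups of 2, taken from the sample titles. Control cells were untreated. The other group was deprived of oxygen and glucose (OGD) for 45 min and returned to normal medium and air for 24 h, a form of ischemic preconditioning.

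The authors deposited 1 table per library, listing the same 20524 transcripts in each, with whole-number read counts and FPKM values (fragments scaled by transcript length and library total) side by side, per the file headers. Of these transcripts, 16906 carry NONCODE identifiers, 1181 Ensembl identifiers and 2437 identifiers in StringTie's format. HISAT2 and StringTie are named in the submitters' processing notes, without versions. The program that counted the reads, and whether it used the strand, are not given in the sources used here. The submitters' processing notes name the mouse build mm9, whereas the tables list 20 autosomes, more than the mouse has, and rat Ensembl identifiers, and reach position 282490960 on chromosome 1. Coordinates are therefore printed as the tables give them, without a build name.

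The deposited FPKM values served only to recover the library total behind them. In every library, all transcripts above 0 gave the same total within 0.1%. These totals were 24949814 and 26371055 for control replicates 1 and 2, and 24934040 and 25016962 for OGD replicates 1 and 2. The lncRNA counts made up 10.4%, 9.98%, 10.6% and 10.0% of them, in that order.

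Counts of transcripts that share a gene name or gene identifier on 1 chromosome were summed, giving 17282 loci, 15124 of them with a single transcript. Names came, in order of preference, from the Ensembl column, StringTie gene identifiers, RefSeq accessions, AceView gene names and the transcript identifier. The RefSeq gene table of assembly GRCr8 was used for names only, and it held the names of 2717 tested loci as a symbol or former name, 2448 of them with a symbol other than a LOC or RGD number. Of the 2717, 2680 bear the name of a protein-coding gene. Such a locus is a listed noncoding transcript at that gene, and its counts could include reads of the messenger RNA. Summing by name also joined transcripts far apart, and 12 loci spanned over 1 Mb.

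Loci were tested with edgeR 4.0.16 in R 4.3.3, by filterByExpr, TMM normalization and the quasi-likelihood F test on group alone. The Benjamini-Hochberg adjusted p threshold was 0.05 over 9578 loci. Because the tables hold lncRNAs, the planned test of all genes and that of lncRNA genes are the same test. Standard errors of log2 fold changes are approximate, computed as the absolute log2 fold change divided by the square root of F. CPM are TMM-normalised and cover the tested loci, as mean and SD of 2 libraries. Ratios of summed counts were scaled by the TMM-adjusted library totals and have exact 95% binomial intervals. The floor for a group at 0 was 3 counts over the group. Both the intervals and the floor cover counting error only. A count of 3 in 1 library corresponds to 1.13 to 1.19 CPM of all lncRNA counts. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, where at least 5 loci were tested.

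Groups, tests, alternatives, 28 gene lists and the rule for named genes were fixed before the data were examined. By that rule the text names, per direction, up to 10 loci with a gene symbol and 5 of any kind. They have the largest change past the threshold, a mean of at least 20 counts in 1 group and no overlap of groups. Remaining places were filled by the smallest unadjusted p and are said not to have passed. Members of the list of named lncRNAs and of the cell type marker lists are also named. A locus taken by this rule and a marker list are not reported here. Lists of coding genes were not to be run on lncRNA tables; running them on loci that carry their names was chosen after seeing the data and is given in the closing observations.

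The steps were tested on simulated counts for the 9578 loci, of which 200 were changed. At 2-fold 0% of 50 loci were called, at 4-fold 50%, and at 16-fold and 64-fold 100%. Of 9378 unchanged loci, 7 were called. Simulated loci had the spread of the fitted trend, without a spread of their own or a structure by replicate number. The 200 changed loci also ease the adjusted threshold. These shares therefore need not hold for the real loci: Syn1 at 49.6-fold and speyrar at 66.3-fold did not pass. Alternatives were DESeq2 1.42.0, other scalings, other filters and thresholds, transcripts without summing, the replicate number as a block and each library left out. Figures were drawn with matplotlib.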

Results

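The series asked which lncRNAs differ between cortical astrocytes preconditioned by OGD and untreated astrocytes. The lncRNA counts per library were 2607020 and 2631684 in control replicates 1 and 2, and 2646300 and 2513804 in OGD replicates 1 and 2. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

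The libraries were compared first across the 9578 tested loci. Libraries with the same replicate number were closest, with Pearson r = 0.931 between control 1 and OGD 1 and 0.928 between control 2 and OGD 2. The correlation was 0.905 between the controls and 0.911 between the OGD libraries. These correlations are across loci, which are not independent replicates. The first principal component held 46.4% of the variance and separated replicate numbers, and the second held 29.4% and separated control from OGD. The third held 24.2% and separated control 1 and OGD 2 from control 2 and OGD 1, a division that follows neither label. Each pair of libraries differed beyond sampling noise, with a chi-square per locus of at least 8.37.

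**Figure D1:**
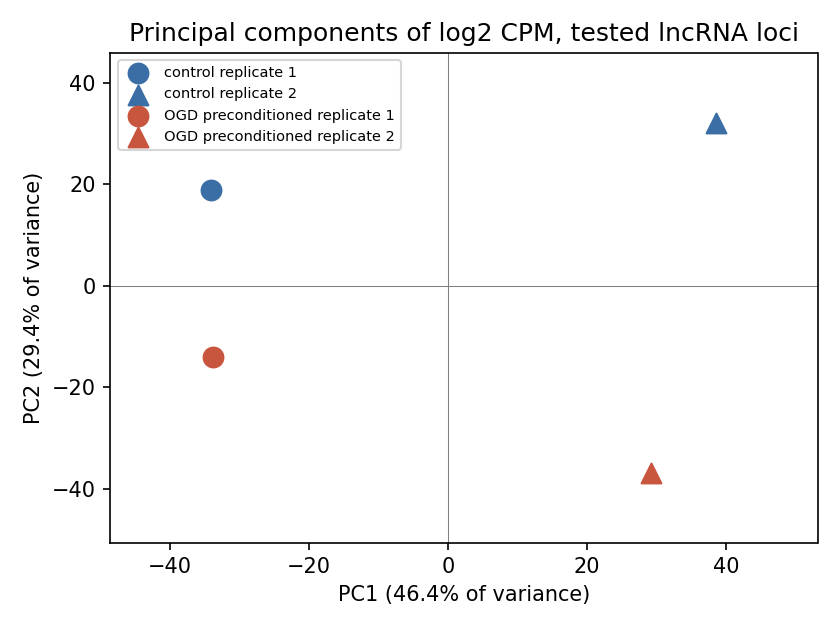
Principal components of log2 CPM over the tested lncRNA loci, 1 point per library, with the share of variance on each axis. Color marks the group and shape the replicate number. The horizontal axis (46.4% of variance) separates replicate numbers and the vertical axis (29.4%) separates control from OGD.

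After OGD and 24 h of reoxygenation, 4 loci rose and 4 fell, each by at least 8-fold, with no overlap between groups. The noncoding transcript at Mdk (chromosome 3, 80841981 to 80843497), the gene of the heparin-binding growth factor midkine, rose from 1.51 ± 0.441 to 144 ± 33.8 CPM (SD, n = 2 per group). The locus blermu (chromosome 11, 57404767 to 57405178) fell from 972 ± 564 to 0.794 ± 0.0571 CPM (SD, n = 2). The transcript at Gtf3c1 (chromosome 1, 197032472 to 197053384), which encodes a subunit of the RNA polymerase III factor TFIIIC, fell from 122 ± 12.1 to 0.605 ± 0.323 CPM (SD, n = 2).

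By edgeR's quasi-likelihood test, Mdk had a log2 fold change of 6.53 (SE 0.37, adjusted p = 0.0307). The locus syby (chromosome X, 77020429 to 77026190) rose from 15 and 20 counts to 1102 and 996, a log2 fold change of 5.94 (SE 0.28, adjusted p = 0.0225). Of the 2 transcripts summed there, 1 had 1 and 1 counts in control and 1087 and 987 after OGD. The locus bloyjo (chromosome 15, 34531435 to 34531850) rose from 1 and 1 to 192 and 218 counts. Its summed counts, scaled by library total, were 213-fold higher, with a 95% counting interval of 58.7 to 1767. RGD1311154, whose current RefSeq symbol is Kctd17 (chromosome 7, 119656408 to 119657434), rose from 2 and 2 to 184 and 198 counts. Both had an adjusted p of 0.0225 in edgeR.

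Among the loci that fell, Gtf3c1 went from 311 and 327 counts to 1 and 2. That is 204-fold lower by summed counts scaled by library total, with a 95% counting interval of 69.6 to 994. The adjusted p was 0.0225 in edgeR. Counts of blermu were 1577 and 3441 in control and 2 and 2 after OGD. The locus nubo (chromosome X, 116752819 to 116754309) fell from 312 and 429 to 7 and 8 counts. Both blermu and nubo had an adjusted p of 0.0465, as did sharza. The last, on chromosome 4 from 49387632 to 49388935, fell by 3.26 on the log2 scale (SE 0.22), from 136 ± 6.08 to 14.1 ± 1.29 CPM (SD, n = 2).

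**Figure D2:**
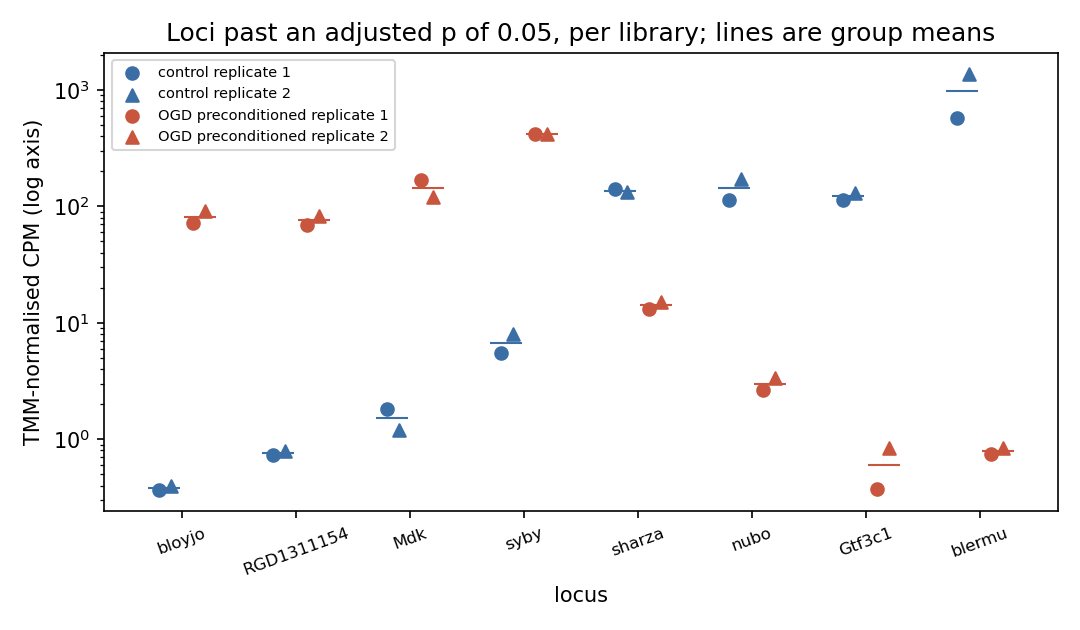
TMM-normalised CPM on a log axis for the 8 loci past the threshold, 1 point per library, with lines at the group means. Both OGD libraries lie above both controls at bloyjo, RGD1311154, Mdk and syby, and below them at sharza, nubo, Gtf3c1 and blermu.

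A total of 224 of the 9578 loci, a share below 0.05, had an unadjusted p under 0.05 in edgeR, 119 higher and 105 lower after OGD. The same test gave 1584 loci between replicate numbers. It gave 171 for the crossed split, which sets control 1 and OGD 2 against control 2 and OGD 1. The groups did not overlap at 28.0% of loci, and chance gives 33.3% for 2 against 2 where the 3 splits are equally likely, which the division by replicate number leaves unsure. The calls, but not the directions of the 8 loci, changed when a library was left out: 0 loci passed without control replicate 1, without control replicate 2 or without OGD replicate 1, with 353, 265 and 257 at an unadjusted p under 0.05, and 12 passed without OGD replicate 2, 5 of them among the 8. On the log2 scale blermu moved from -10.18 to -9.41 without control replicate 2 and Gtf3c1 from -7.56 to -8.17 without OGD replicate 2. DESeq2 called 38 loci, among them all 8, whereas edgeR called 0 without a filter on low counts and 1 (at syby) when transcripts were not summed.

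**Figure D3:**
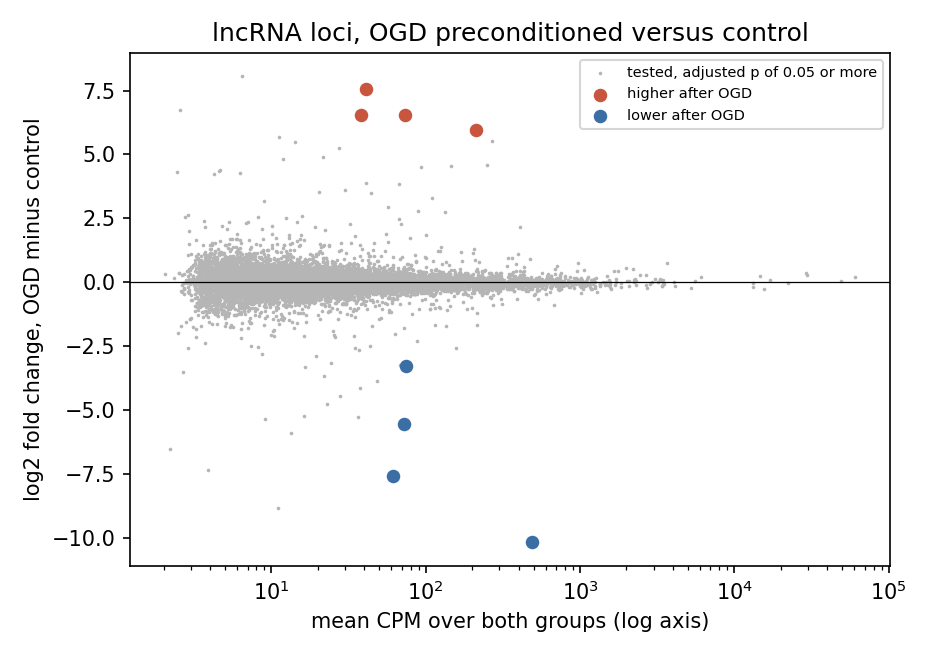
Log2 fold change of OGD over control against mean CPM on a log axis, 1 point per tested locus. The 4 loci that rose and the 4 that fell are colored, and the remaining tested loci are grey.

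Other symbol-bearing loci were higher after OGD in both libraries without passing edgeR's adjusted threshold in the fit on group alone. Matn3, named for an extracellular matrix protein, measured 7.29 ± 2.08 CPM in control and 81.6 ± 13.7 CPM after OGD (SD, n = 2; adjusted p = 0.0941). Cox7a2l, named for a factor in the assembly of respiratory supercomplexes, measured 148 ± 5.87 and 665 ± 114 CPM (SD, n = 2; adjusted p = 0.0996). It overlaps NONRATT024782.2, with 282 and 101 counts in control and 3 and 6 after OGD, and merging overlapping loci, chosen after seeing the data, moved its log2 fold change from 2.17 to 1.60 (adjusted p = 0.447). Fars2 had 2 and 2 counts in control and 49 and 66 after OGD (adjusted p = 0.110). Syn1, named for a synaptic vesicle protein, had 2 and 1 counts in control and 98 and 45 after OGD, a ratio of 49.6 with a 95% counting interval of 16.6 to 243 (adjusted p = 0.185). Phldb3 had 0 counts in both controls and 33 and 32 after OGD. That is 22.5-fold higher against a floor of 3 counts over the group, with a lower exact 95% counting limit of 17.8. Plagl2, Sypl and Daam1 had log2 fold changes of 2.46 (SE 0.37), 2.79 (SE 0.51) and 1.46 (SE 0.28). Sypl was at 3.70 without control replicate 1. Without a symbol, blyko was at 7.81 ± 0.232 CPM in control and 177 ± 57.5 CPM after OGD (SD, n = 2; adjusted p = 0.0560). Of the loci in this group, Matn3, Cox7a2l, Fars2, Syn1, Phldb3, Plagl2, Sypl and blyko passed in DESeq2. In edgeR with the replicate number as a block, Matn3, Cox7a2l, Syn1 and blyko passed. The labels do not say what that number marks.

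Symbol-bearing loci lower after OGD that did not pass included Ctf8, now Chtf8, at 42.4 ± 5.35 CPM in control and 9.52 ± 0.685 CPM after OGD (SD, n = 2; adjusted p = 0.230 in edgeR). Glipr1 had 23 and 18 counts in control and 0 in both OGD libraries. That is 13.1-fold lower against a floor of 3 counts over the group, with a lower exact 95% counting limit of 10.2. Whsc1, now Nsd2 and a histone methyltransferase gene, had a log2 fold change of -1.89 (SE 0.37). Adam23 stood at -1.67, Plxnb2 at -1.46, Cdkn2aip at -1.41, Dst at -1.07, Dcun1d1 at -1.03 and Mknk1 at -0.94. The same merging moved Cdkn2aip to -0.26. Without a symbol, speyrar had 67 and 71 counts in control and 1 and 1 after OGD, a ratio of 66.3 with a 95% counting interval of 18.0 to 553 (adjusted p = 0.0560). Ctf8, Adam23 and speyrar passed in DESeq2, and speyrar also in edgeR with the replicate number as a block.

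Well-known lncRNAs formed the list fixed for these tables, and 8 loci matched by name to its 53 members were tested. By edgeR, 0 passed over all loci and 0 adjusted over the list alone, where the smallest adjusted p was 0.610; the smallest unadjusted p was 0.0762, and DESeq2 called 0 of the 7 to which it gave an adjusted p. Meg3, listed as RGD1566401, measured 664 ± 157 CPM in control and 731 ± 195 CPM after OGD (SD, n = 2). Tug1 measured 445 ± 40.0 and 403 ± 37.1 CPM, Gas5 356 ± 48.7 and 344 ± 50.5 CPM, and Miat 61.4 ± 9.58 and 75.0 ± 1.61 CPM. Snhg11, listed as RGD1563912, had the largest log2 fold change of the list at 1.10 (SE 0.49), on 5 and 6 counts in control and 11 and 12 after OGD. Terc stood at 0.81 (SE 0.63), and at 1.71 without control replicate 1. The loci listed as Snhg8 and Rmrp, which the RefSeq table gives as other names of Uqcc5 and Rpph1, stood at 0.08 (SE 0.38) and 0.00062 (SE 0.19). Both may therefore be other genes than the list means, and both are kept in its tests. The median log2 fold change of the 8 was 0.11, with camera p = 0.133 and p = 0.260 with an estimated correlation; fry, which compares no other loci, gave p = 0.196, and p = 0.0395 for change in either direction.

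The most abundant locus was AC134224.1, with 5.64% ± 0.0385 of lncRNA counts in control and 6.38% ± 0.102 after OGD (SD, n = 2). A 7SK locus, of the small nuclear RNA that binds the elongation factor P-TEFb, followed with 4.83% ± 0.255 and 4.85% ± 0.887. Rn7sl1, the RNA of the signal recognition particle, took 2.24% ± 0.411 and 2.14% ± 0.262. The 10 most abundant loci held at most 27.1% of counts in any library, and 0 of them passed the threshold. Among the 10, AC134224.1, AC134224.2, AC134224.3, gokla and stawflu lie between 221151827 and 221158792 on chromosome 1, and some overlap. They need not be separate transcripts. Mean shares in control and after OGD were 2.70% and 3.17% for gokla and 2.58% and 3.19% for AC134224.3. They were 1.67% and 1.39% for AC134224.2, and 1.35% and 1.54% for stawflu.

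Loci named after cell type markers were noncoding transcripts at the marker genes. Sums over a list include loci with too few counts to be tested, and 0 of the tested loci passed the threshold. The 7 loci of astrocyte markers summed to 59.1 ± 13.7 CPM in control and 71.7 ± 24.8 CPM after OGD (SD, n = 2), led by Gfap, the astrocyte intermediate filament gene, at 30.3 ± 8.54 and 36.8 ± 22.0 CPM. Fibroblast and meningeal names summed to 253 ± 129 and 255 ± 99.8 CPM, led by Col1a1 at 195 ± 115 and 186 ± 87.2 CPM. Neuron names summed to 109 ± 19.6 and 120 ± 7.26 CPM, led by Gria2 at 95.4 ± 20.1 and 81.5 ± 15.7 CPM. Syn1 is among them, at 0.563 ± 0.233 and 27.8 ± 12.8 CPM, and its difference exceeds that of the sum. Microglia and macrophage names, with Ptprc highest, summed to 51.2 ± 14.3 and 40.5 ± 25.3 CPM. Endothelial and mural names summed to 6.37 ± 2.83 and 28.9 ± 4.92 CPM, through Abcc9 with 6 and 17 counts in control and 85 and 54 after OGD (log2 fold change 2.61, SE 0.58, adjusted p = 1.00). Ependymal names summed to 4.96 ± 5.33 and 5.52 ± 6.04 CPM. Names of genes raised in all reactive astrocytes, with Vim highest, summed to 207 ± 1.26 and 199 ± 30.2 CPM. Names of A1-type and A2-type reactive genes had means at or below 3.44 CPM in both groups, and 0 of their loci had enough counts to be tested.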

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

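Merging loci with overlapping transcripts and scaling to the totals implied by FPKM were chosen after seeing the data. The count of 8 changed loci became 38 with DESeq2, 0 without a filter on low counts (404 loci at an unadjusted p under 0.05), 159 at an unadjusted p under 0.05 with at least 2-fold, and 1 with transcripts as deposited. Leaving out each library in turn gave 0 to 12, with the lone library assumed to vary like the other group. With the replicate number as a block, 21 loci passed, among them all 8 and Matn3, Cox7a2l, Syn1, blyko and speyrar; the labels do not say what the number marks, and deviations of same-numbered libraries from their group means correlated at 0.300 across loci. The other 6 settings gave 7 to 10 loci, with 7 or 8 of the original 8 among them. The cause of these shifts was not tested, except that an unfiltered test covers 16703 loci and a left-out library leaves 3. The 8 loci kept their direction under every alternative that gave them a value, and 43 such values no longer passed. The camera p of the named lncRNA list lay between 0.104 and 0.969 and kept its side of 0.05. Of 445 values of named loci, 367 kept direction and side, 20 newly passed and 15 changed sign, for loci that had not passed. Rmrp, near 0 throughout, was at -0.0063 with DESeq2, -0.0059 with the replicate block, -0.0048 with DESeq2 size factors, -0.0037 without a filter, -0.0035 as deposited, -0.0018 with overlapping loci merged and -0.0089 with totals implied by FPKM, and between -0.14 and 0.14 with a library left out. With a library left out, RGD1566401 lay between -0.15 and 0.41, Gas5 between -0.20 and 0.11 and Snhg8 between -0.19 and 0.43; the cause was not tested. Alternatives set for normalized values (pseudocounts, FPKM in place of TPM) and for rows absent from a table had nothing to act on. At this depth and number of libraries, simulated 2-fold changes with the spread of the fitted trend were called at 0% of loci.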

Other observations

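The tests of library depth and of the list without Acat2 were set before their results were seen; the other tests here were chosen afterwards. Loci named after genes of coding lists were also tested by camera, for the 9 coding lists with at least 5 such loci, adjusting over 10 lists. Of these, 1 passed at the preset correlation. The loci named after cholesterol synthesis genes were higher after OGD as a list by limma camera, with an adjusted p of 8.4e-04. The unadjusted camera p with an estimated correlation was 0.0599. By fry, the unadjusted p was 0.0684 for a shared direction and 3.8e-04 for change in either direction. With the replicate number as a block, camera gave p = 7.6e-04, and p = 0.180 with an estimated correlation. All 5 loci of the list had a log2 fold change above 0. Hsd17b7, a sterol synthesis enzyme gene, measured 6.51 ± 1.49 CPM in control and 17.8 ± 6.84 CPM after OGD (SD, n = 2), and Srebf2, which encodes the transcription factor of the pathway, 15.5 ± 1.80 and 29.7 ± 5.42 CPM. Acat2, Hmgcs1 and Sc4mol had log2 fold changes of 2.36 (SE 0.76), 0.26 (SE 0.67) and 0.13 (SE 0.63). By edgeR 0 of the 5 passed over all loci, and 3 passed adjusted over the list alone. The NRF2 and antioxidant list, with Ftl1 at 1497 ± 172 and 2032 ± 221 CPM, had an adjusted camera p of 0.205. Adjusted camera p was 0.313 for oxidative phosphorylation and for the unfolded protein and integrated stress response, 0.619 for astrocyte markers, for neurotrophic and growth factors and for p53 targets, 0.791 for ribosomal proteins and 0.909 for HIF targets.

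Between replicate numbers, 127 loci differed by edgeR's adjusted p. The transcript at Lox, the gene of a collagen cross-linking enzyme, had 4 counts in each number 1 library and 3202 and 2684 in the number 2 libraries, a log2 fold change of 9.61 (SE 0.19, adjusted p = 9.1e-05). That at Map4, named for a microtubule-associated protein, had 382 in each number 1 library and 2 in each number 2 library (adjusted p = 3.2e-04). Vegfa measured 316 ± 43.6 CPM in number 1 and 885 ± 44.3 CPM in number 2 libraries (SD, n = 2; adjusted p = 0.0182), and Col1a1 119 ± 7.09 and 262 ± 20.4 CPM (adjusted p = 0.0287). Of the 10 lists run between replicate numbers, 1 passed, HIF target genes, which holds Lox and Vegfa. Its adjusted p by limma camera was 0.00618, with an unadjusted p of 0.0731 at an estimated correlation, and its median log2 fold change was 0.02.

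A first pattern is that 4 of the 8 changed loci (bloyjo, RGD1311154, Gtf3c1 and blermu) have at most 3 counts in each library of 1 group. At syby the sum does not, but 1 of its 2 transcripts does, with 1 and 1 counts in control. The tables argue against reads counted at an overlapping lncRNA locus, since 0 of the 8 overlap a transcript of another listed locus. Counts that switch on or off without following a label may account for part of it: of loci with at most 3 counts in 2 libraries and at least 30 in the other 2, 12 divide by group, 9 by replicate number and 8 across both. A switch by preconditioning stays open, since 12 of 29 is not distinguishable from 1 in 3 (exact one-sided binomial p = 0.232). That test takes the loci as independent and the 3 splits as equally likely, which the division by replicate number leaves unsure. Reads assigned to coding transcripts, which were not analysed here, stay open too. Of the 3 splits of the libraries, 2 gave at least the real 8 loci, the real one and that by replicate number with 127, and the crossed split gave 0; 3 splits are too few for a share under 0.05, and the 127 point to a structure of the libraries by number.

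A second pattern is that structure itself. The depth of lncRNA counts did not follow the number, with 2607020 and 2646300 counts in number 1 and 2631684 and 2513804 in number 2 libraries. Other measures did follow it. Transcripts above 0 numbered 18121 and 18135 in number 1 and 17629 and 17752 in number 2 libraries. Loci with at least 10 counts were 9577 and 9492, and 9063 and 9031. The totals implied by FPKM were 24949814 and 24934040, and 26371055 and 25016962. Whether these differences underlie the structure was not tested. Thinning every library to 2513804 counts removed at most 5.01% of a library. After it, 111 loci were called, 110 of them among the 127. A thinning this small moves too little to decide whether the depth of lncRNA counts underlies the 127. A different cell mixture could not be excluded: loci named after astrocyte markers had a mean log2 fold change of -0.54 in number 2 against number 1 libraries, and Col1a1 was higher there. The list gave a camera p of 0.0810. Separate cultures or days may also underlie the numbers, which the labels leave unsaid, and were not tested.

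The last pattern is the cholesterol list. Acat2 sums transcripts 6.45 Mb apart, with 90 counts in OGD replicate 2 and 30 in OGD replicate 1. The transcript starting at 54423184 had 64 and 6 of these, in that order, and 2 and 1 counts in control replicates 1 and 2. The other transcript had 26 and 24, and 16 and 6. The list without Acat2 had a camera p of 0.00288 at the preset correlation, which argues against that locus as the whole cause. Whether members vary together is left open, since the estimated correlation, 0.0146, is near the preset and its p of 0.0599 does not bear on it; the list's camera p was 0.0866 without control replicate 2. An effect of preconditioning and reads of the host messenger RNAs cannot be told apart from each other here, since coding transcripts were not analysed.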
